A study of Homo sapiens with 5 samples.

How the data were processed

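Gene expression was measured in HepG2 cells on 5 two-colour oligonucleotide arrays. Per the labels, cells were treated for 24 h with a plant extract at 75 µg/mL, and cells given 1‰ DMSO were the control. On every array the RNA of treated cells carried Cy5 and the RNA of DMSO-treated cells carried Cy3, and no array had the dyes swapped. Per the labels' protocols, total RNA was extracted with Trizol, amplified, reverse transcribed with random primers and labelled by Klenow extension.

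Each array's deposited tables hold, per oligo, the ratio of treated over DMSO signal, as computed by the authors. A second pair of deposited tables per array holds the oligos that the authors listed as changed by at least 2-fold, once by oligo and once by RefSeq accession, with equal ratios line by line. The deposited value table of the whole series holds log2 ratios as processed by the authors. It has 37632 spots per array, of which 73.1% to 73.7% are blank. Set against the oligo tables, at least 99.8% of the oligo ratios were found in it as log2 of the same ratio at the number of decimals deposited, so its scale and direction are those of the oligo tables. Its column medians were 0.017 for Dayi, 0.025 for Lichuan, 0.026 for Shizhu, 0.040 for Yaan and -0.0033 for Yunnan. Whether and how the arrays were centred stays unknown. The array platform, the scanner, the normalization and the rule that left spots blank are not given in the sources used here. Spot intensities were not used here. The number of arrays limits the precision.

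From these files the log2 of each ratio was taken, repeat spots of one oligo were averaged, and spots without an oligo name (19 to 35 per array) were left out. The tables named 10403 oligos on at least 1 array and 8129 on all 5. Gene symbols came from the pairing of oligo and RefSeq accession in the authors' lists, looked up without version numbers in a table of RefSeq genes for assembly GRCh38.p14. Of 2211 listed oligos, 1708 had 1 symbol, 13 had several and 490 had none, and none was named from an oligo with several. Oligos of one symbol were averaged, which left 8056 genes or unnamed oligos with a value on all 5 arrays, called genes hereafter, of which 1441 had a symbol. Of the 70 symbols with several oligos, 0 had oligos of opposite sign and 1, CENPA, had oligos differing by more than 1 on the log2 scale. Because only oligos that the authors listed at 2-fold or more on at least 1 of these arrays have a name here, named genes are enriched for change. Genes with no name here were tested but belong to no gene list, and a gene that is not named here may be unchanged or unmeasured. No coordinates are given, since the files name no genome build.

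The 4 R. coptidis arrays formed one group and the R. serra array another. A linear model with a mean for each group was fitted to the log2 ratios of all 5 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 3 residual and 5.815 prior degrees of freedom. The R. coptidis mean was tested against 0, and the R. serra value against the R. coptidis mean. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 change of at least 1 in size. DMSO was the reference channel and counts as 1 control sample, so a test against 0 leaves out the control's own spread and any dye effect of a gene. These cancel between the extracts as far as the DMSO RNA was the same on each array, which is not given in the sources used here. The single R. serra array was assumed to vary like the R. coptidis arrays. The R. coptidis replicates differ in growing region, so their spread includes the region. Nothing in the labels says that the cultures were separate, so p-values measure only the spread between these samples, which may be technical. R. serra against DMSO, the counts per array, the overlaps, the correlations and the growing regions were described without a test. The correlations were set beside 100 simulations of unchanged samples that share 1 control.

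A total of 35 gene lists were fixed before the data were examined, as were the tests, the alternatives in processing and the rule for named genes. Named members of a list are hereafter those with a symbol and a value on all 5 arrays. Members blank on any array, such as the R. serra array, are not counted. Lists with at least 5 named members (13 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01. The background was the other named genes, with Benjamini-Hochberg adjustment over the lists. The design had foreseen all measured genes as the background, and named genes were used because no other gene can be placed in a list. List members carry a name only because they passed 2-fold on these same arrays, so the number of changed members is not independent evidence of a list's direction. The rule for named genes took the 10 highest and 10 lowest called means with a symbol and 1 sign on all 4 arrays for R. coptidis. It took likewise 10 and 10 for R. serra against R. coptidis, with the R. serra value outside the range of the R. coptidis arrays. It took the 5 highest and 5 lowest R. serra ratios, the 3 genes farthest above and the 3 farthest below the other regions for each region, and up to 4 members of each list with the largest change. Some genes were always to be given, among them INSIG1, CYP1A1, DDIT3, TRIB3, CDKN1A, CCND1 and ALB. Of these 7 only CYP1A1, TRIB3 and CDKN1A could be named, and the other genes were not analysed here. Some genes that the rule takes are not reported here. Members printed outside this rule were taken from the lists after their values were seen.

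The scripts were tested on simulated data with 8056 genes. For R. coptidis against DMSO, 99% of 100 genes changed by 1.5 on the log2 scale and 100% of 100 genes changed by 2 were called, with 0 false calls. For R. serra against R. coptidis, the shares were 88% and 99%, with 3 false calls. The simulated arrays carried independent noise with the SD between the R. coptidis arrays, and no error from a shared control or from the dyes. These shares and false calls therefore say nothing about such errors, which a test against 0 leaves in. Alternatives tried were centring, quantile normalization, a robust spread, other fold thresholds, oligos taken singly, values needed on only 3 R. coptidis arrays with none needed on the R. serra array, each replicate left out, rank tests and estimated correlations for the lists, and, chosen after seeing the data, all spots of the series value table. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used for tables and plots.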

Results

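Transcript levels were measured in HepG2 cells, an established human line derived from a hepatocellular carcinoma, after 24 h with plant extract at 75 µg/mL. Extracts of R. coptidis (Rhizoma coptidis, the dried rhizome of Coptis, whose best-known alkaloid is berberine) came from 4 growing regions. Dayi was replicate 1, Lichuan replicate 2, Shizhu replicate 3 and Yaan replicate 4. One further extract, of the plant material that the labels name R. serra, came from Yunnan. Each extract was hybridised on 1 array against RNA of DMSO-treated cells, so that the R. coptidis group had n = 4 and R. serra n = 1. The study asked how the response to R. coptidis compares between growing regions. The arrays gave ratios for 9216 to 9459 oligos each, and 8056 genes had a value on all 5 arrays. The number of arrays limits the precision. Values below are log2 ratios of treated over DMSO cells, with the SD over the 4 R. coptidis arrays.

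R. coptidis changed the expression of 1401 genes against DMSO, of which 669 were higher and 732 lower. With genes included that had values on at least 3 of the 4 R. coptidis arrays, whether or not on the R. serra array, the split turned to 913 higher and 823 lower. The ranks that follow are among named genes with a value on all 5 arrays. CYP1A1, a cytochrome P450 that the aryl hydrocarbon receptor induces, rose the most, by 141-fold (log2 7.14 ± 0.35, n = 4, adjusted p = 8.62e-10, limma). Among these genes, the transcripts next in size were DUSP5, a phosphatase that acts on ERK (5.49 ± 0.38, 45.0-fold), the scaffold protein gene AKAP12 (5.35 ± 0.23) and AREG, a ligand of the EGF receptor (4.86 ± 0.20). GDF15, a stress-induced secreted factor, rose 25.1-fold (4.65 ± 0.33), and the water channel gene AQP3 rose by 4.62 ± 0.20. The transcription factor EGR1 (4.36 ± 0.19), the cell cycle inhibitor CDKN1A (4.11 ± 0.52, 17.2-fold), RASD1 (4.08 ± 0.14) and SLC16A6 (3.92 ± 0.08) completed the 10 highest of these genes. Some genes with no value on the R. serra array had higher R. coptidis means, such as TAGLN3 (6.26 ± 0.24).

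The lowest named transcripts with a value on all 5 arrays included several that encode plasma proteins made by the liver. FGA, the fibrinogen alpha chain, stood at -3.90 ± 0.41 (15.0-fold lower, adjusted p = 1.93e-08). Haptoglobin (HP) stood at -3.17 ± 0.28, thyroxine-binding globulin (SERPINA7) at -3.09 ± 0.25, the carboxypeptidase gene CPB2 at -2.98 ± 0.28 and corticosteroid-binding globulin (SERPINA6) at -2.90 ± 0.07. HP has a near-identical paralog, HPR, so its value is uncertain. The others of the 10 lowest were the Wnt receptor gene FZD4 (-3.17 ± 0.21), PAQR8 (-3.07 ± 0.61), TMEM37 (-3.03 ± 0.18), the mitotic kinesin gene KIF20A (-2.96 ± 0.20) and NR1H4, which encodes the bile acid receptor FXR (-2.95 ± 0.36). All 20 genes had 1 sign on the 4 arrays, which the rule that took them required.

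**Figure D1:**
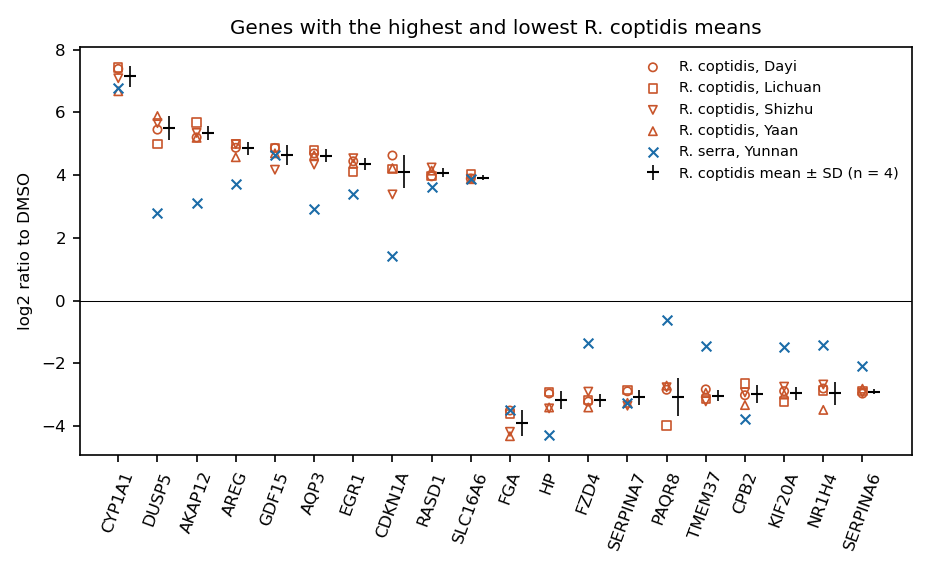
Log2 ratios to DMSO (vertical axis) of the 10 highest and 10 lowest R. coptidis means among named genes with a value on all 5 arrays. Open symbols are the 4 R. coptidis arrays, bars the mean ± SD (n = 4) and crosses the single R. serra array. The crosses of GDF15 (4.65) and SLC16A6 (3.86) lie close to the R. coptidis means, and that of DUSP5 (2.78) lies well under its mean of 5.49.

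Genes of several stress programmes rose together with R. coptidis. Being called is common among named genes: of all 1441, 510 were called higher and 535 lower with R. coptidis. The counts of called members in each list are to be read beside these. Each of the 9 named immediate early genes rose, with EGR1 and DUSP5 as above, IER3 at 3.09 ± 0.24 and KLF6 at 2.48 ± 0.25 (list adjusted p = 0.00148, camera). In the list of the integrated stress response, the ATF4 programme of amino acid and protein stress, 9 of 11 named members rose and 2 were not called (adjusted p = 0.00128). ATF3 rose by 3.65 ± 0.42, the cystine transporter gene SLC7A11 by 3.48 ± 0.43, SESN2 by 2.98 ± 0.17 and TRIB3 by 1.71 ± 0.25. Of 14 named targets of NRF2, the regulator of antioxidant genes, 12 rose (adjusted p = 0.000959), among them AKR1B10 (2.93 ± 0.23), SRXN1 (2.74 ± 0.16) and GCLM (2.37 ± 0.20). HMOX1, also on that list, had 1.05 ± 0.25 and was not called without replicate 2 (0.93) or after quantile normalization (0.99). Of 11 named p53 targets, 8 rose (adjusted p = 0.0135), with GADD45A at 3.71 ± 0.20, PLK3 at 3.07 ± 0.24 and RRM2B at 2.38 ± 0.14, while BAX had -0.59 ± 0.43 and was not called. With an estimated correlation none of these lists passed: adjusted p = 0.207 for the immediate early, ATF4 and NRF2 lists and adjusted p = 0.264 for p53. The full lists hold 18 immediate early, 26 ATF4, 18 NRF2 and 18 p53 genes.

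Genes of cell division fell. Of 28 genes in the mitosis list 19 were named members, and all 19 were lower (list adjusted p = 6.29e-05). AURKB stood at -2.61 ± 0.32, DLGAP5 at -2.34 ± 0.15 and CCNB2 at -2.33 ± 0.16. Of 17 named genes of DNA replication, 15 were lower (adjusted p = 0.000456). CCNA2 stood at -2.49 ± 0.39, GINS2 at -2.34 ± 0.17, the helicase subunit gene MCM2 at -2.27 ± 0.17 and the primase gene PRIM1 at -2.18 ± 0.22. TYMS, at 0.22 ± 0.13, and PCNA, at -0.998 ± 0.23, were not called. Both lists had adjusted p = 0.231 with an estimated correlation.

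Genes of lipid synthesis and of the secretory pathway also fell. In the cholesterol list 9 of 11 named members were lower (adjusted p = 0.0135), including ACAT2 (-1.56 ± 0.14), FDPS (-1.41 ± 0.10), IDI1 (-1.31 ± 0.17) and HMGCS1 (-1.30 ± 0.08). Of 6 named genes of fatty acid synthesis, 4 were lower (adjusted p = 0.0249), with PNPLA3 at -2.54 ± 0.17, MLXIPL at -1.30 ± 0.09, FADS2 at -1.28 ± 0.15 and FASN at -1.23 ± 0.17. This list was lost on ranks (adjusted p = 0.0542). Of 16 listed chaperone genes of the endoplasmic reticulum 6 were named members, and all 6 were lower (adjusted p = 0.0157). HSPA5 stood at -1.82 ± 0.35 and MANF at -1.66 ± 0.14. Of 10 named hepatocyte secreted proteins 8 were lower (adjusted p = 0.00271), with FGG at -2.57 ± 0.29 and FGB at -2.38 ± 0.21. With an estimated correlation these lists had adjusted p = 0.207 for cholesterol and chaperones, adjusted p = 0.231 for fatty acid synthesis and adjusted p = 0.264 for secreted proteins.

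**Figure D2:**
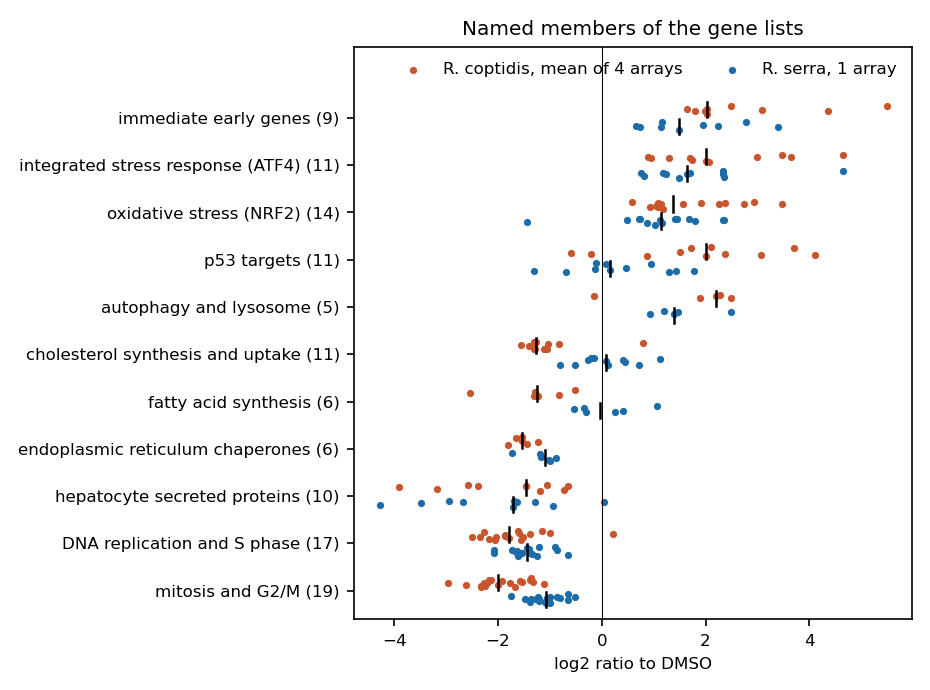
Log2 ratios to DMSO (horizontal axis) of the named members of 11 gene lists, with the number of members in brackets. Each point is a gene, upper points the R. coptidis mean of 4 arrays and lower points the R. serra array, and the black bars are medians. The p53 median is 2.01 for R. coptidis and 0.15 for R. serra, and the cholesterol medians are -1.26 and 0.089.

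In the remaining tested lists, 2 of 9 named genes of glycolysis rose and 2 fell (adjusted p = 0.381, and 0.438 with an estimated correlation), with LDHA at -1.44 ± 0.07 and NDRG1 at 1.31 ± 0.14. Of 5 named TGF-beta and matrix genes, 3 rose and 1 fell (adjusted p = 0.513, and 0.624 with an estimated correlation). CCN1 stood at 2.70 ± 0.14 and COL4A1 at -1.84 ± 0.28. Of 5 named autophagy genes 4 rose, with GABARAPL1 at 2.48 ± 0.29 and SQSTM1 at 2.21 ± 0.22, and the list missed the threshold (adjusted p = 0.0636, and 0.231 with an estimated correlation). It passed on ranks (0.0108) and without replicate 2 (0.0487). Adjusted over the list alone, the number of called members was that given over all genes for each of these 13 lists. Members are named here because the authors listed them at 2-fold or more on these arrays, so the counts are not independent evidence of a direction.

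Lists with fewer than 5 named members were not tested as lists. Of 10 listed aryl hydrocarbon receptor targets 4 were named members, and all 4 rose, with NQO1 at 1.58 ± 0.11 and TIPARP at 1.49 ± 0.10 beside CYP1A1. Of the xenobiotic metabolism genes ABCC2 (2.39 ± 0.07) and ALAS1 (1.48 ± 0.45) rose, and SULT2A1 (-1.11 ± 0.16) and GSTA1 (-1.07 ± 0.09) were lower. Of the PPARA targets PLIN2 rose (1.32 ± 0.13), FABP1 was lower (-2.57 ± 0.45) and CPT2 was lower (-1.13 ± 0.72) but not without replicate 2 (-0.77). The hepatocyte transcription factor genes CEBPA (-2.43 ± 0.10), NR1H4 and ONECUT1 (-1.05 ± 0.09) were lower, as were the 3 named acute phase genes HP, FGB and SERPINA3 (-1.21 ± 0.11). The cytokine genes CXCL8 (3.87 ± 0.36) and CCL20 (1.60 ± 0.11) rose. So did the apoptosis regulators HRK (2.49 ± 0.18), MCL1 (2.23 ± 0.29) and PMAIP1 (1.95 ± 0.21), but not BCL2L1 (0.95 ± 0.07). OAS1 (1.38 ± 0.08), MT2A (1.66 ± 0.11), the ribosome biogenesis genes DDX21 (1.10 ± 0.14) and NOLC1 (1.10 ± 0.10) and the histone gene H1-2 (1.56 ± 0.05) rose. Of the named heat shock genes only HSPA1B was called (-1.06 ± 0.15, and -0.99 and not called without replicate 4). Its near-identical copy HSPA1A had -0.96 ± 0.20, so both values are uncertain. GSTA1 (-0.99), HSPA1B (-0.98) and ONECUT1 (-0.97) did not reach 2-fold after quantile normalization. Of the housekeeping genes YWHAZ rose (1.39 ± 0.14) and TUBB was lower (-1.17 ± 0.04). Single named members stood for gluconeogenesis (PCK2, -0.16 ± 0.13), bile acid transport (SLC51B, -0.78 ± 0.37) and the respiratory chain (UQCRC2, -0.91 ± 0.10), none of them called. Markers of other cell types had 1 named fibroblast gene, ACTA2 (1.09 ± 0.06, called), and 1 leukocyte gene, LYZ (-0.87 ± 0.21, not called). The 4 lists of G1 cyclins, cytosolic ribosomal proteins, proteasome subunits and endothelial markers had 0 named members with a value on all 5 arrays. They were not analysed here. CDKN2B (1.40 ± 0.15) of the G1 list and ESAM (1.88 ± 0.25) of the endothelial list were blank on the R. serra array alone.

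Counts of changed genes lay close together across the 4 growing regions. On single arrays 721 genes were at least 2-fold higher and 795 at least 2-fold lower with the Dayi extract, 708 and 730 with Lichuan, 636 and 713 with Shizhu, and 696 and 726 with Yaan. The means were 690.2 ± 37.6 higher and 741 ± 36.7 lower genes (SD, n = 4). Of 904 genes that were 2-fold higher with at least 1 region, 500 were so with all 4, and of 987 lower genes 538 were. Independent lists of these sizes would share 0.43 and 0.57 genes. Across genes, which are not independent replicates, the log2 ratios of region pairs correlated with a mean Pearson r of 0.967 (0.962 to 0.972) and a covariance of 0.667. Unchanged samples that share a control gave r = 0.50 and a covariance of 0.018 in simulation. Samples and control were given equal noise, which fixes that r in advance, so it tests nothing. The noise was the residual spread between these arrays. It leaves out dye effects and any control error common to all arrays, so the simulated covariance may be too low a baseline. The controls could not be split, so part of the excess over either value may come from the shared controls.

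**Figure D3:**
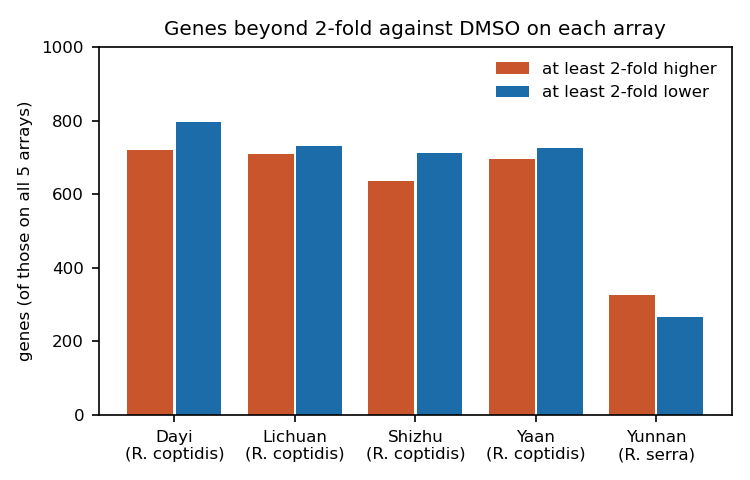
Number of genes (vertical axis, of 8056 with a value on all arrays) at least 2-fold higher or lower than in DMSO-treated cells on each array. The 4 R. coptidis arrays have 636 to 721 higher and 713 to 795 lower genes, and the R. serra array has 325 and 265.

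Few genes set one region apart from the mean of the other 3 by 2-fold or more. There were 8 such genes for Dayi, 4 for Lichuan, 2 for Shizhu and 2 for Yaan, and with 1 array per region these differences have no test. The 6 named genes farthest from the other regions are given for each region, whether or not they reach 2-fold. Those that did were SMG8, CCDC106 and BST2 for Dayi, LURAP1L, CPT2 and PAQR8 for Lichuan, HPR for Yaan and 0 named genes for Shizhu. With the Dayi extract SMG8 stood at 2.44 against 0.74 ± 0.19 (SD, n = 3) in the other regions, B3GNT3 at 2.19 against 1.36 and SRP68 at 1.35 against 0.64. CCDC106 stood at -1.73 against -0.63 ± 0.10, BST2 at -1.09 against -0.06 and PYCR3 at -2.86 against -1.95. With the Lichuan extract LURAP1L stood at 3.61 against 2.56 ± 0.45, HPR at -2.22 against -3.03 and TOP2A at -1.43 against -2.20. CPT2, a carnitine palmitoyltransferase of the mitochondria, stood at -2.20 against -0.77 ± 0.14, PAQR8 at -3.98 against -2.77 ± 0.07 and RSAD1 at -1.71 against -0.79. The Shizhu extract gave -1.44 for PYCR3 against -2.43, 2.68 for JUN against 1.81, and -1.10 for IGDCC3 against -1.93. It gave 3.38 for CDKN1A against 4.35 ± 0.24, -2.65 for TOP2A against -1.80 and 0.54 for SMG8 against 1.38. With the Yaan extract IGFBP1 stood at 3.84 against 2.96 ± 0.14, AP2B1 at 1.34 against 0.62 and RGS10 at 3.41 against 2.74. HPR, whose value is uncertain for the reason given for HP, stood at -3.81 against -2.50, PIMREG at -3.28 against -2.44 and LURAP1L at 2.26 against 3.01. The R. coptidis mean of SMG8 (1.17 ± 0.86) was not called without replicate 1 (0.74), and that of RSAD1 (-1.02 ± 0.49) was not called without replicate 2 (-0.79) or after quantile normalization (-0.95).

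On its single array, which has no replicate check and no p-value, R. serra took fewer genes beyond 2-fold of DMSO than any R. coptidis array did. A total of 325 genes were at least 2-fold higher and 265 at least 2-fold lower. CYP1A1 was again the highest named gene (6.77, 109-fold), followed by GDF15 (4.65), SLC16A6 (3.86), AREG (3.71) and RASD1 (3.63). The lowest were HP (-4.28), HPR (-4.11), CPB2 (-3.78), FGA (-3.48) and SERPINA7 (-3.27). TRIB3 stood at 2.33 and CDKN1A at 1.44. With quantile normalization, which gives this array the wider spread of the others, 1248 genes passed 2-fold.

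The genes that were 2-fold higher on all 4 R. coptidis arrays included 215 that were so with R. serra, and of the lower ones 188 were. Independent lists would share 20.2 and 17.7. Across genes the R. serra ratios correlated with those of the R. coptidis arrays with a mean r of 0.729 (0.703 to 0.761), a covariance of 0.349 and a slope on the R. coptidis mean of 0.518, beside the simulated r of 0.50 and covariance of 0.018. Part of the excess may come from the shared controls here too, and the limits of the simulation given for the region pairs hold. Of the 669 genes that rose with R. coptidis, 241 (36.0%) were at least 2-fold higher with R. serra and 48 had the opposite sign. Of the 732 that fell, 211 (28.8%) were at least 2-fold lower and 66 had the opposite sign. These shares leave out oligos blank on the R. serra array alone. Of such oligos, 173 were at least 2-fold higher and 10 at least 2-fold lower with R. coptidis. The share for higher genes therefore cannot be set against that for lower genes.

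R. serra differed from R. coptidis in 587 genes, 337 of which were higher and 250 lower with R. serra. Among these were 186 genes that rose and 231 that fell with R. coptidis. In 185 and 229 of them R. serra was nearer 0 or of the opposite sign. The placental growth factor gene PGF showed the largest difference among named genes, with 3.15 ± 0.28 for R. coptidis (n = 4) and -0.14 for R. serra (difference -3.29 ± 0.22 SE, adjusted p = 0.00014, limma). IER5 (3.17 against 0.38), GADD45A (3.71 against 0.94), DUSP5 (5.49 against 2.78) and CDKN1A (4.11 against 1.44) were also lower with R. serra. So were OTUB2 (3.81 against 1.21), the glucuronosyltransferase gene UGT2B7 (2.53 against -0.01), ATF3 (3.65 against 1.18) and TIGAR (2.46 against 0.08). HMOX1, which encodes haem oxygenase 1, was the 1 gene beyond 2-fold in opposite directions, with 1.05 ± 0.25 for R. coptidis and -1.44 for R. serra (difference -2.50 ± 0.20 SE, adjusted p = 0.000197). Its R. coptidis mean lay at the threshold, with 1.03 for Dayi, 1.41 for Lichuan, 0.90 for Shizhu and 0.87 for Yaan. That mean was not called without replicate 2 or after quantile normalization.

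The 10 named genes with the largest differences in the other direction had fallen with R. coptidis and were within 2-fold of DMSO with R. serra. PAQR8 stood at -3.07 ± 0.61 against -0.63 (difference 2.44 ± 0.41 SE, adjusted p = 0.00231), the sulfate transporter gene SLC26A2 at -1.96 against 0.32 and the potassium channel gene KCNJ2 at -2.17 against 0.06. PNPLA3 stood at -2.54 against -0.53, BOC at -2.89 against -0.90, ARFRP1 at -1.96 against 0.01 and B9D1 at -1.92 against -0.02. The matrix genes TNC (-1.82 against 0.13) and COL4A1 (-1.84 against 0.06) and the hepatocyte transcription factor gene CEBPA (-2.43 against -0.56) completed the 10.

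**Figure D4:**
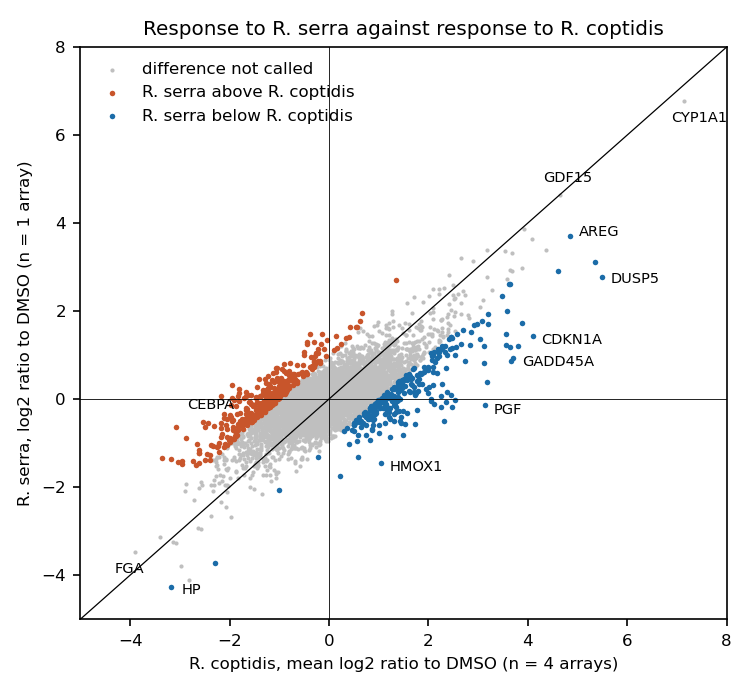
Log2 ratio to DMSO of the single R. serra array (vertical axis) against the mean log2 ratio of the 4 R. coptidis arrays (horizontal axis) for 8056 genes, with the line of equal values. Coloured points are the 337 genes called higher and the 250 called lower with R. serra. CYP1A1 lies close to the line, at 7.14 and 6.77, and PGF lies far below it, at 3.15 and -0.14.

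Of the 13 gene lists tested, p53 targets had the lowest adjusted p for this difference. Of 11 named members 9 were lower with R. serra, with a median difference of -1.56 (list adjusted p = 0.00026). RRM2B stood at 0.15 with R. serra against 2.38 ± 0.14, ZMAT3 at -0.12 against 2.10 ± 0.38 and TP53I3 at 0.08 against 1.72 ± 0.24. The cholesterol list was higher with R. serra, with a median difference of 1.15 and 7 of 11 named members called (adjusted p = 0.000392), such as FDPS (0.45 against -1.41) and DHCR7 (0.72 against -1.06). In fatty acid synthesis 4 of 6 were higher (median difference 1.36, adjusted p = 0.00206), among them FASN (0.26 against -1.23) and GPAM (1.07 against -0.51). Mitosis genes had a median difference of 0.90, and 6 of 19 were higher (adjusted p = 0.000392), with KIF20A at -1.47 against -2.96 and CENPF at -0.86 against -2.17. Immediate early genes had a median difference of -0.97 with 3 of 9 lower (adjusted p = 0.00438), and NRF2 targets had -0.45 with 3 of 14 lower (adjusted p = 0.0271). With an estimated correlation none of the 6 lists passed: adjusted p = 0.290 for p53, cholesterol, fatty acid synthesis and immediate early genes, adjusted p = 0.439 for mitosis and adjusted p = 0.359 for NRF2. After quantile normalization the mitosis (adjusted p = 0.154), immediate early (0.424) and NRF2 (0.961) lists were also lost.

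The other 7 tested lists did not pass in this contrast. ATF4 genes had a median difference of -0.15 (adjusted p = 0.342), with ATF3, SESN2 (1.71 against 2.98) and SLC7A11 (2.34 against 3.48) lower. GDF15 differed by -0.002 ± 0.24 SE (adjusted p = 0.996). Adjusted p was 0.387 for chaperones, 0.342 for DNA replication, 0.434 for secreted proteins, 0.517 for autophagy, 0.915 for glycolysis and 0.990 for TGF-beta and matrix. TYMS was lower with R. serra (-1.74 against 0.22), as was PCNA (-2.07 against -0.998), and PRIM1 was higher (-0.65 against -2.18). APOB, the main apolipoprotein of LDL, was higher (0.05 against -1.47). WIPI1 was higher (1.48 against -0.14), and so were PCK2 (1.25 against -0.16), SLC51B (0.81 against -0.78) and NR1H4 (-1.41 against -2.95). CXCL8 (1.73 against 3.87), H1-2 (-0.32 against 1.56), PMAIP1 (0.65 against 1.95), YWHAZ (0.16 against 1.39) and ACTA2 (-0.21 against 1.09) were lower. MT1A was higher (1.11 against 0.10; difference 1.01, and 0.99 and not called without replicate 1).

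Some calls between the extracts depended on scaling or on 1 replicate. The R. serra ratios were smaller across genes (slope of 0.518 on the R. coptidis mean), so a difference in a gene or list may be part of a smaller response on the whole. AREG was lower with R. serra by 1.15, a difference that became 0.0045 with the opposite sign after quantile normalization (adjusted p = 0.987). Quantile normalization also ended 18 of the 58 calls of named genes examined in this contrast, among them AQP3 (-0.77), KIF20A (0.92), NR1H4 (0.90), HMGCS1 (0.96), SLC7A11 (-0.31), SESN2 (-0.49), PMAIP1 (-0.91), CCNA2 (0.53, adjusted p = 0.260), GABARAPL1 (-0.44, adjusted p = 0.154) and RSAD1 (0.98). CCNA2 (1.10) was also not called without replicate 3 (0.93). GABARAPL1 (-1.09) was also not called without replicate 3 (-0.95), and RSAD1 (1.05) not without replicate 1 (adjusted p = 0.0532) or 2 (0.82).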

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

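The test of the spots as controls was chosen after their ratios were seen. The rule that decided the test of array position was also changed after its value was seen, as said where it is given.

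Differences between the extracts passed a test of the difference itself in 587 genes and, at camera's preset correlation, in 6 gene lists, with R. serra on a single array. With an estimated correlation 0 lists passed (adjusted p = 0.290 to adjusted p = 0.439 for these 6), and quantile normalization left 3. The median R. serra minus R. coptidis differences were 1.145 for cholesterol, 1.363 for fatty acid synthesis, -0.4504 for NRF2 targets, -1.562 for p53 targets, 0.8952 for mitosis and -0.9663 for immediate early genes. HMOX1 differed by -2.496.

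On single R. coptidis arrays 7 of 149 groups of 4 values had 1 sample far from the others, and chance gives about 1 in 20, here 7.45. The groups include genes picked because 1 region lay farthest from the other 3, such as CCDC106 and PAQR8. The chance rate does not hold for those genes. SLC16A6 stood at 4.042 with Lichuan (others 3.87 to 3.89) and PAQR8 at -3.982 with Lichuan (others -2.84 to -2.71). CCDC106 stood at -1.728 with Dayi (others -0.74 to -0.56) and PFKP at 1.239 with Yaan (others 1.08 to 1.10). With Shizhu SRXN1 stood at 2.494 (others 2.81 to 2.83), IRF9 at 0.433 (others 1.12 to 1.27) and the median of the chaperone list at -1.39 (others -1.60 to -1.57).

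Many genes changed the same way with both extracts: 452 of the genes called for R. coptidis (241 higher and 211 lower) were also beyond 2-fold with R. serra. An offset that every array carries, from the dyes or the DMSO RNA, would give both extracts equal ratios. The share of these genes that differ between the extracts at adjusted p under 0.05 was 44.9%. Its exact binomial 95% interval was 40.3% to 49.6%, over genes, which are not independent. An offset alone was taken to allow at most 5%, so an offset alone does not account for all of the 452 genes. The share does not exclude a partial offset, as an offset with a difference between the extracts on top could give it too. Over all genes 3200 of 8056 passed the same cutoff, so the share is not particular to these genes. Of the 203 that differ, 181 had R. serra nearer 0. An offset together with the smaller spread of the R. serra array is therefore not excluded for them. For the 249 genes that did not differ, an offset cannot be told apart from a shared response, because no dye swap or second control sample was available to decide. A response shared by both extracts stays open for them, untested.

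The series value table holds 526 spots outside the oligo tables that have a value on all 5 arrays, and 266 of these were at least 2-fold lower and 64 at least 2-fold higher on every array. Position on the array was argued against: 52 oligo spots in the same range of spot numbers had a mean log2 ratio of 0.040 (SE 0.089). Its upper bound of 0.22 lies below the 0.42 that position would need. The rule first set also asked for the value to lie within 0.1 of 0 by more than its spread, which it does not meet, and by that rule the test was undecided. The slope of R. serra on R. coptidis over these spots was 0.970 (95% interval 0.958 to 0.983), against 0.518 for genes. This restates that the spots carry like ratios on all arrays, so it does not bear on whether they are control spots with fixed input in both channels, which stays open. What the spots hold is not given in the sources used here, and no biological explanation was tested.

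Oligos that were blank on the R. serra array and measured on all 4 R. coptidis arrays numbered 318, of which 173 were at least 2-fold higher and 10 at least 2-fold lower with R. coptidis. Blanks unrelated to level were argued against: oligos on all 5 arrays split into 694 higher and 757 lower (Fisher's exact test, two-sided, p = 4.85e-39). Among oligos blank on 1 R. coptidis array and measured on the other 4 arrays, the split was 13 higher and 76 lower (Fisher's exact test, two-sided, p = 4.85e-42). That second set may itself be chosen by level, in the opposite direction, so it is not a neutral baseline. A filter on dim signal may have left these spots blank, as the ratio of higher to lower oligos of 17.30 lies above the 3 that such a filter was taken to need. Under that explanation their level with R. serra was low, and a biological difference between the extracts in these genes stays open, untested.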

How the results depend on the processing

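The alternative that used all spots of the series value table was chosen after seeing the data. Leaving out each R. coptidis replicate gave 1378 to 1435 genes for R. coptidis against DMSO, 559 to 618 for R. serra against R. coptidis, 10 to 11 passing lists for R. coptidis and 6 in each case for the contrast. Centring, a robust spread, oligos taken singly and values needed on 3 R. coptidis arrays moved neither count of genes by over 1.5 times. With values needed on only 3 of the 4 R. coptidis arrays and not on the R. serra array, 1736 genes were called, of which 913 were higher and 823 lower, so that higher genes made up 52.6% of calls in place of 47.8%. With quantile normalization 1232 genes were called for R. coptidis, all of them among the 1401, and 628 for the contrast, of which 385 were among the 587. By construction, other thresholds moved the counts. For R. coptidis there were 6664 genes on adjusted p only, 3009 at 1.5-fold and 2204 with treat, and for the contrast 3200, 1953 and 285. At 1.5-fold the single arrays of Dayi, Lichuan, Shizhu and Yaan had 3202, 3057, 2975 and 3080 genes, and at 3-fold 542, 497, 453 and 495. All spots of the value table, which hold more spots, gave 2406, 2278, 2133 and 2329. R. serra against DMSO had 1681 genes at 1.5-fold, 1248 after quantile normalization, which widens this array's spread, and 1106 over all spots. The overlap of the 4 regions was 2353 genes at 1.5-fold, and 208 differences between regions passed 1.5-fold. The mean correlation of R. coptidis pairs was 0.9595 with Spearman and 0.9714 without the least changed genes, and that of R. serra with R. coptidis was 0.6502 with Spearman. The cause was not tested. With an estimated correlation 0 lists passed for R. coptidis and 0 for the contrast, where camera's preset gave 10 and 6, and quantile normalization left 3 in the contrast. AREG between the extracts reversed to 0.004453 after quantile normalization (adjusted p = 0.987), and the cause was not tested. Of the 116 genes called for R. coptidis that the rule for named genes took, 5 lost the call after quantile normalization and 0 after centring. The filter on dim spots was not run, as no intensities were used, so what signal over background limits is not known. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.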

Other observations

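The tests in this part were chosen before the result was seen. The genes named were chosen after their values were seen.

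Oligos measured on all 4 R. coptidis arrays and blank on the R. serra array lay outside the main tests. Of 318 such oligos, 173 were at least 2-fold higher and 10 at least 2-fold lower with R. coptidis. A gene name was present for 116, of which 100 were at least 2-fold higher and 3 at least 2-fold lower. Such an oligo could get a name only if the authors listed it at 2-fold or more with R. coptidis. The share of named oligos beyond 2-fold therefore follows from the naming. Among the named oligos, TAGLN3 had the highest mean log2 ratio (6.26 ± 0.24, SD, n = 4, 76.5-fold), followed by SERPINB2, a serine protease inhibitor (5.61 ± 1.01). PTHLH, which encodes parathyroid hormone-related protein, had 4.42 ± 1.34, and ALDH3A1, on the list of aryl hydrocarbon receptor targets, had 4.16 ± 0.68. The immediate early gene FOS had 3.69 ± 1.06, MDM2, the p53 target that limits p53, had 3.51 ± 0.48, and PPP1R15A had 3.09 ± 0.61. The p53 target FAS had 0.89 ± 0.18. The 3 lower genes were FAM111A (-2.65 ± 0.34), the flap endonuclease gene FEN1 (-2.30 ± 0.36) and MTTP, needed to assemble lipoproteins (-1.66 ± 0.29). These genes entered a test only in the alternative that needs no value on the R. serra array, and their own adjusted p values are not given here.

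The few genes that set 1 growing region apart may reflect array noise of the size seen on spots outside the oligo tables. Between 1 region and the other 3, 14 of 8056 genes (0.174%) and 1 of 526 such spots (0.19%) differed by at least 2-fold (Fisher's exact test, two-sided, p = 0.613). With 1 such spot the shares are too few to decide, so noise and a difference between regions cannot be told apart for these genes, and a difference between regions stays open, untested.

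R. serra was beyond 2-fold of DMSO in 137 genes whose R. coptidis mean was within 2-fold, and 28 of these differed between the extracts.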
